A study of Mus musculus with 9 samples.

How the data were processed

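Total RNA of mouse cells was labelled with biotin by a whole-transcript protocol and measured on 9 Affymetrix arrays, 3 each for ESC, D5 and D10. Per the labels, all cells grew on feeder cells, and the replicates are biological. Groups were taken from the sample titles. Per the submitters' processing notes, MAS5 was used, with no version named. The between-array normalization is not given in the sources used here.

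The deposited values are on a log2 scale, judged from the authors' short table, whose linear intensity values equal 2 to the power of the log2 values to within rounding. The deposited log2 values ran from 0.70 to 13.82 over 28853 probe sets, and the 9 arrays had medians between 4.45 and 4.53. Both deposited log2 tables held identical values. The authors' larger table also gives a p-value and a step-up p-value per comparison, and the authors' short table of 461 selected probe sets gives intensity means, a ratio (fold) and a p-value per comparison. Those authors' columns were described, not used for tests. In the short table, the 3 columns named as standard deviations were equal in all 461 probe sets and were not used, and the p-value for ESC against D5 matched the pairwise test within 5% in 0.651% of them.

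Probe sets were named through RefSeq accessions and symbols of the mouse GRCm38.p6 gene table: 18873 by accession, 2487 by symbol and 1740 by an older symbol. The file's own name was kept for 2023, and 3730 stayed unnamed. For tests by gene, the probe set with the highest mean over the 9 arrays stood for each of 22319 genes. All 28853 probe sets were tested without a filter, and no control probe sets were marked. As a background level served the 95th percentile of 1397 olfactory and vomeronasal receptor probe sets, 3.71 on the log2 scale, which 18290 probe sets exceeded on average. Arrays have no read depth; their number limits the precision.

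Arrays were compared before any test. D10 replicates 1 and 3 correlated at r = 0.9977 over probe sets, against 0.9924 to 0.9945 in the other 8 pairs within groups, and were averaged into 1 sample. The design fixed beforehand had all 9 arrays counted separately, and that fit became an alternative. Each comparison used limma 3.58.1 in R 4.3.3 (lmFit and eBayes) on the log2 values, with a mean per group over 8 samples, 5 residual and 3.56 prior degrees of freedom. Tests were two-sided with Benjamini-Hochberg adjustment over all probe sets of a comparison and a threshold of 0.05.

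The 27 gene lists were fixed before the data were examined, and 699 of their 719 names matched a probe set. Each list with at least 5 members was tested with limma's camera at a preset correlation of 0.01, adjusted over the lists, and again with an estimated correlation and with fry. Chromosomes with at least 20 genes were tested as sets in the same way; with so many genes the preset correlation makes camera insensitive, so medians are given. Members were also counted with p adjusted over the list alone.

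Genes were named by a rule fixed beforehand. It takes the 6 largest rises and falls with adjusted p under 0.05 whose arrays did not overlap between groups. Predicted genes and olfactory and vomeronasal receptors are left out. Clone-type names (EG, BC or AK with digits, for example) were left out too, which the rule did not state. It adds up to 2 members of each list with the largest change past the threshold, and Pou5f1, Nanog, Sox2, Zfp42, Klf4 and Esrrb always. Where more than 30 genes came up, fewer list members were named. The rule then keeps members of lists past the set test, but members of other lists, such as Ebf1, Ptpn6 and Laptm5, were named too. Col1a1, Irf7, Xist, Sgce, Ccn2 and Col5a2, which the closing section names, were chosen after their values were seen.

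The fits were tested on 1 simulated data set with the real means and spreads and independent noise. In it, 100 probe sets above the background level were changed by each of 2 sizes. The shares recovered therefore do not cover dimmer probe sets, and all shares rest on 1 draw. For D5 against ESC, 32% of changes of 0.5 and 99% of changes of 1 on the log2 scale were recovered. For D10 against ESC the shares were 13% and 98%, and for D10 against D5 94% of changes of 1. Unchanged probe sets made up 4.38% of the calls for D5 against ESC, 9.52% for D10 against ESC, above the nominal 5%, and 4.33% for D10 against D5. Changes against the shared ESC arrays were set beside 100 simulated data sets without effects. Alternatives planned beforehand were quantile normalization, median centring, leaving out the lowest 30% of probe sets, an intensity trend with robust estimation, only the arrays of the groups compared, array weights, the replicate number as a block, and leaving out each array. Added after seeing the data were the 9 arrays counted separately, the interquartile range as a covariate, a t-test of 3 arrays against 3 as in the authors' larger table, chromosomes with only genes above the background level, and the ESC arrays split 2 and 1 between D5 and D10, where the single array takes its spread from the other groups. Tables and figures were made with Python 3.11.15, NumPy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.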

Results

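Gene expression was measured in mouse embryonic stem cells (ESCs) and in a pair of cell lines re-derived from them, with 3 arrays for each of 3 groups. The ESC line came from 3.5-day blastocysts and carried the Oct4-EGFP transgene, which gives green fluorescence in pluripotent cells. These ESCs were transplanted into mice. Green cells were sorted from the bone marrow and grown on feeder cells into the D5 line, taken on day 5 after transplantation, and the D10 line, taken on day 10. The comparisons ask how far each re-derived line differs from the ESCs that were transplanted, and how far the re-derived lines differ from each other.

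D10 replicates 1 and 3 were nearer to each other than any other arrays of the same group. Over the 8292 probe sets with a mean log2 value above 6, the standard deviation (SD) of their difference was 0.0686, against 0.154 to 0.201 in the other 8 pairs within groups. They differed by less than the noise between other replicates and were counted as 1 sample, so that D10 has n = 2 and ESC and D5 have n = 3. The labels name the arrays biological replicates, and the sample titles speak of cell lines in the plural, but each re-derived group is described as 1 line. With 1 line per group, the p-values measure the spread between samples of a line, not between independent derivations. Whether the replicates were separate lines is not settled by the labels. The small number of arrays limits the precision of the p-values.

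Compared with ESCs, the D5 line had much lower levels of interferon-response genes and higher levels of fibroblast and stroma genes (the latter list with adjusted p = 0.0514 with an estimated correlation), while the core pluripotency factors moved little. Irgm1, a GTPase of cell-autonomous immunity, went from a log2 value of 8.10 ± 0.06 (SD, n = 3) in ESC to 4.50 ± 0.10 (SD, n = 3) in D5, which is 12.1-fold lower (limma, adjusted p = 5.07e-06). The noncoding RNA H19, expressed from the maternal allele, was 3.53-fold higher, at 10.64 ± 0.07 against 8.82 ± 0.06 (SD, n = 3 each, limma, adjusted p = 3.29e-05). Pou5f1 (Oct4) had a log2 change of -0.19, which did not pass the test (limma, adjusted p = 0.302), though it passed with an intensity trend and robust estimation (adjusted p = 0.0481).

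Of 28853 probe sets, 1116 passed an adjusted p of 0.05 in limma, 682 higher and 434 lower in D5. Of these, 141 changed at least 2-fold, 65 up and 76 down. The largest falls by the fixed rule were Irgm1, the RNA helicase Ddx60 (log2 change -3.17), Rtp4 (-2.95), the interferon-induced GTPase Tgtp1 (-2.59) and the oligoadenylate synthetase family members Oasl2 (-2.46) and Oas1g (-2.44). The largest rises were the protease inhibitor Serpina3m (1.88), H19 (1.82), the matrix protein Efemp1 (1.51), the protocadherin Pcdh19 (1.42), the surface antigen Ly6a (1.40) and Anxa5 (1.38). Tgtp1, Oas1g and Ly6a belong to families with near-identical copies, so their values are uncertain as to the family member. The D5 levels of Ddx60 (2.66), Rtp4 (3.10) and Tgtp1 (3.25) lay below the background level of 3.71, so their falls are lower bounds and their order is uncertain. Of the 12 genes, Ly6a alone lost its call in an alternative (highest adjusted p = 0.0652).

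Of 33 measured interferon-response genes, 22 fell, 0 rose and 11 did not pass, and 25 fell when adjusted over the list alone. In 22 of the 33 the mean over arrays lay above the background level, and a fall of a dimmer gene may not show in either re-derived line. The list's median log2 change was -0.99 (camera, adjusted p = 6.40e-34, and adjusted p = 0.00678 with an estimated correlation). Genes of class I antigen presentation went the same way, with 3 of 24 down, 21 not past the threshold and a median of -0.27 (camera, adjusted p = 2.06e-06, and adjusted p = 0.0227 with an estimated correlation). The class I gene H2-T10 fell by 1.27 and the immunoproteasome subunit Psmb8 by 0.81 on the log2 scale, the latter to a level below background (3.47) and with its call lost without some of the samples (highest adjusted p = 0.0773). In antigen presentation 13 members fell and 1 rose when adjusted over the list alone.

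Of 35 fibroblast and stroma genes, 24 rose, 0 fell and 11 did not pass, and 30 rose when adjusted over the list alone. Their median log2 change was 0.80, or 1.74-fold (camera, adjusted p = 6.40e-34, and adjusted p = 0.0514 with an estimated correlation). Thy1, a surface protein of fibroblasts, rose by 1.28 (SE 0.09) and the smooth muscle actin Acta2 by 1.17 (SE 0.11) on the log2 scale. Beside this rise, 12 of 38 imprinted genes rose, 1 fell and 25 did not pass, with a median of 0.26 (camera, adjusted p = 9.03e-11, and adjusted p = 0.00678 with an estimated correlation). The imprinted genes up numbered 19 and those down 1 when adjusted over the list alone. The growth factor gene Igf2, the imprinted neighbour of H19, was 2.26-fold higher.

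The Y-linked list also passed the set test in the samples with the higher fibroblast level (median 0.25, camera, adjusted p = 0.0254, and adjusted p = 0.179 with an estimated correlation). Of its 9 members 1 rose, Ddx3y, by 0.84 on the log2 scale, and 8 did not pass, with 1 up when adjusted over the list alone. The call of Ddx3y was lost in several alternatives (highest adjusted p = 0.0926), and 4 of the 9 members lay above background.

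Naive pluripotency genes shifted slightly down. Of 27, 6 fell, 0 rose and 21 did not pass, with 11 falls when adjusted over the list alone and a median of -0.20 (camera, adjusted p = 2.13e-07, and adjusted p = 0.189 with an estimated correlation). The growth factor gene Fgf4 fell by 0.65 and Tdgf1, a Nodal co-receptor, by 0.52 on the log2 scale. Nanog fell by 0.43 (limma, adjusted p = 0.0156) and Sox2 by 0.35 (limma, adjusted p = 0.0439). The call of Sox2 was lost with median centring and with only the arrays of the groups compared, and those of Nanog, Fgf4 and Tdgf1 were each lost without at least 1 of the samples (highest adjusted p = 0.0676, 0.0933 and 0.0560). Zfp42 (-0.17), Klf4 (-0.01) and Esrrb (-0.18) did not pass.

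Glycolysis and hypoxia genes shifted down as a list, with 11 of 33 down, 1 up and 21 not past the threshold (median -0.27, camera, adjusted p = 1.30e-09, and adjusted p = 0.0938 with an estimated correlation). Of these genes 18 fell and 1 rose when adjusted over the list alone. The mitophagy receptor Bnip3 fell by 1.07 and the phosphofructokinase subunit Pfkl by 1.02 on the log2 scale. Of 30 DNA methylation and chromatin genes 5 fell, among them Dnmt3l (-0.61) and Tet2 (-0.56), whose calls were lost in several alternatives (highest adjusted p = 0.107 and 0.0747). In this list 25 did not pass, and 12 fell when adjusted over the list alone (median -0.14, camera, adjusted p = 0.000690, and adjusted p = 0.353 with an estimated correlation).

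Another 6 lists passed camera, with adjusted p from 0.000690 to 0.0471, and none of them held with an estimated correlation, for which the parentheses give the adjusted p. Upward, beside the fibroblast median of 0.80, these were the p53 targets (median 0.12, 4 of 31 up, adjusted p = 0.206 with an estimated correlation), primitive and visceral endoderm (0.05, 6 of 27 up and 1 down, adjusted p = 0.303), neuroectoderm (0.01, 3 of 25 up, adjusted p = 0.303) and adhesion and homing (0.12, 6 of 32 up and 3 down, adjusted p = 0.333). Downward, they were germ line (-0.19, 2 of 27 down, adjusted p = 0.136) and cell cycle (-0.21, 3 of 37 down and 2 up, adjusted p = 0.397). Adjusted over the list alone, the members up and down were 10 and 0, 8 and 2, 5 and 0, 10 and 7, 0 and 4, and 3 and 11, in the same order.

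Genes of blood cells did not move as a group. The haematopoietic regulators (3 of 36 up and 1 down; camera, adjusted p = 0.684), the abundant bone marrow transcripts (1 of 32 up and 1 down, adjusted p = 0.542) and the haemoglobin list (0 of 9 up and 0 down, adjusted p = 0.972) did not pass. Only 8 of the 32 abundant marrow transcripts lay above the background level of 3.71 on the log2 scale. So did 20 of the 36 haematopoietic regulators and 4 of the 9 haemoglobin genes, and a fall could hardly show in the others. The lists of primed epiblast (0.302), two-cell-like (0.301), mesoderm (0.0581), trophoblast (0.109), FGF-ERK (0.0657), Wnt (0.414), Nodal and BMP (0.568), LIF-STAT3 (0.601), endothelial (0.448) and housekeeping genes (0.301) did not pass camera either (adjusted p in parentheses), although FGF-ERK targets passed upward with fry (adjusted p = 0.0353). Mesoderm genes passed upward in some alternative fit. No chromosome of 20 passed the set test, where camera gave 0 at an unadjusted p under 0.05 with the preset and 1 with an estimated correlation. Medians per chromosome ran from -0.04 to 0.01. Among genes above background the largest absolute median was 0.037, where a gain of 1 copy in all cells would give 0.58. The Y chromosome was not among the 20 tested. The count of 1116 fell to 247 with the pairwise test of 3 arrays against 3 that matches the p-values in the larger table of the authors, and rose to 1695 with an intensity trend and robust estimation. It was 542, 643 and 457 without ESC replicates 1, 2 and 3 in turn, and 510, 607 and 564 without D5 replicates 1, 2 and 3.

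**Figure D1:**
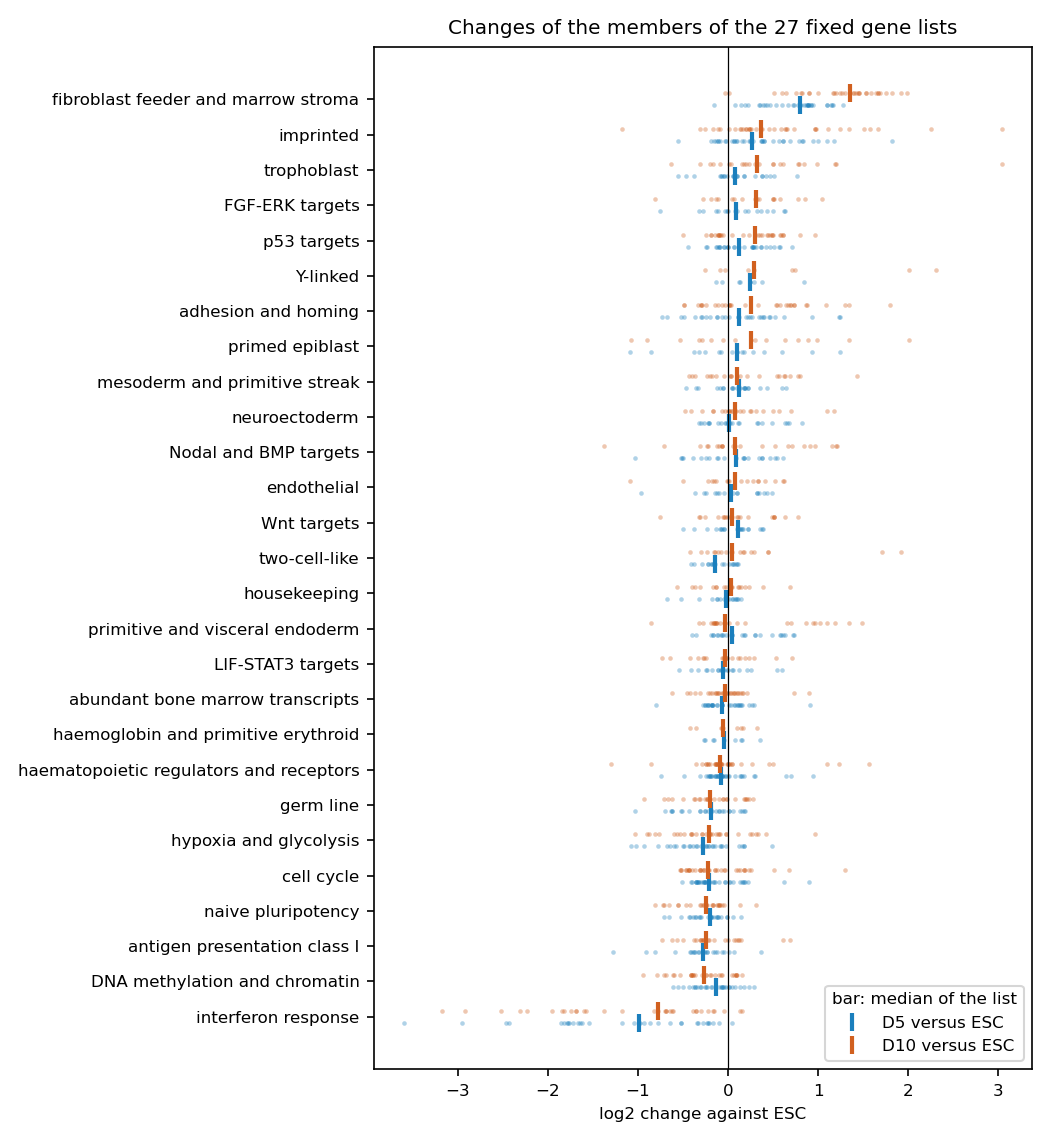
Log2 change against ESC (x axis) of each measured member of the 27 gene lists (rows), as points, for D5 (blue) and D10 (orange), with a bar at each list's median. The interferon list has the lowest medians (-0.99 in D5 and -0.78 in D10) and the fibroblast list the highest (0.80 and 1.36).

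In the D10 line interferon-response genes were again lower than in ESC, and the rise of fibroblast genes had a larger median (D10 against D5, adjusted p = 0.0561 with an estimated correlation). Peg10, 3 of 9 Y-linked genes and 2 of 19 two-cell-like genes rose too. Peg10, an imprinted gene of retrotransposon origin needed in the placenta, went from 6.28 ± 0.07 (SD, n = 3) in ESC to 9.33 ± 0.02 (SD, n = 2) in D10, 8.24-fold higher (limma, adjusted p = 9.23e-06). Irgm1 was 9.02-fold lower, at 4.92 ± 0.24 (SD, n = 2, limma, adjusted p = 1.08e-05). Pou5f1 had a log2 change of -0.31 and did not pass (limma, adjusted p = 0.0796), though it passed in 4 alternatives, with adjusted p down to 0.00334.

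In this comparison 2496 of 28853 probe sets passed limma, 1536 up and 960 down, and 472 of them changed at least 2-fold, 381 up and 91 down. The largest rises were Peg10 (3.04), Ly6a (2.66), the hyaluronan synthase Has2 (2.53), Uty (2.31), H19 (2.25) and Efemp1 (2.22), as log2 changes. The largest falls were Irgm1 (-3.17), Ddx60 (-3.02), Rtp4 (-2.92), the ISG15 protease Usp18 (-2.52), Oas1g (-2.45) and Tgtp1 (-2.35). Uty in ESC (3.07) and Ddx60 (2.81), Rtp4 (3.13), Usp18 (3.13) and Tgtp1 (3.50) in D10 lay below the background level of 3.71, so their changes are lower bounds.

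Interferon-response genes fell in 20 of 33 cases, rose in 0 and did not pass in 13, with 24 falls when adjusted over the list alone (median -0.78, camera, adjusted p = 1.53e-20, and adjusted p = 0.0176 with an estimated correlation). Class I antigen presentation did not pass camera, with a median of -0.25 (adjusted p = 0.0633), but passed downward with fry (adjusted p = 0.00182). Of its members 2 rose, 2 fell and 20 did not pass, and 2 rose and 6 fell when adjusted over the list alone.

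Of the 35 fibroblast genes 33 rose, 0 fell and 2 did not pass, also when adjusted over the list alone. Their median change was 1.36, or 2.56-fold (camera, adjusted p = 4.04e-41, and adjusted p = 0.0340 with an estimated correlation). Thy1 rose by 1.99 (SE 0.10) and the matrix protein Thbs1 by 1.92 (SE 0.14) on the log2 scale. For 31 of the 35 genes the D5 mean lay between those of ESC and D10.

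With this fibroblast rise, 17 of 38 imprinted genes rose, 1 fell and 20 did not pass, and 20 rose and 2 fell when adjusted over the list alone (median 0.37, camera, adjusted p = 3.44e-12, and adjusted p = 0.00999 with an estimated correlation). Trophoblast genes rose in 10 of 24 cases and fell in 1, while 13 did not pass (median 0.32, camera, adjusted p = 5.59e-06, and adjusted p = 0.0261 with an estimated correlation). Peg10 is on both lists, and the helix-loop-helix factor Id2 rose by 1.20 on the log2 scale. Trophoblast genes up numbered 12 and down 1 when adjusted over the list alone. Of the 9 Y-linked genes 3 rose, with Uty at 2.31 and Ddx3y at 2.01, 6 did not pass, and 4 rose when adjusted over the list alone (camera, adjusted p = 0.00346, and adjusted p = 0.114 with an estimated correlation).

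Naive pluripotency genes again shifted slightly down, with 7 of 27 down, 20 not past the threshold, 11 down when adjusted over the list alone and a median of -0.24 (camera, adjusted p = 6.04e-06, and adjusted p = 0.206 with an estimated correlation). Fgf4 fell by 0.81, Dppa4 by 0.72 and Sox2 by 0.43 on the log2 scale, but the call of Sox2 was lost with only the arrays of the groups compared, and that of Fgf4 without 1 of the samples (highest adjusted p = 0.0728). Nanog (-0.18), Zfp42 (-0.17), Klf4 (-0.24) and Esrrb (-0.25) did not pass, except Nanog with an intensity trend and robust estimation (adjusted p = 0.0410). DNA methylation and chromatin genes fell in 12 of 30 cases and 18 did not pass (median -0.27, camera, adjusted p = 5.59e-06, and adjusted p = 0.206 with an estimated correlation). The methylcytosine dioxygenases Tet2 (-0.94) and Tet1 (-0.79) fell, and 14 members fell when adjusted over the list alone. Hypoxia and glycolysis genes fell in 12 of 33 cases and rose in 1, the angiogenic factor Vegfa (0.97), while Bnip3 fell by 1.04 (median -0.21, camera, adjusted p = 0.000474, and adjusted p = 0.206 with an estimated correlation). Of this list 14 members fell and 3 rose when adjusted over the list alone.

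A further 10 lists passed camera in D10 against ESC, with adjusted p from 0.000167 to 0.0393, and none of them held with an estimated correlation, for which the parentheses give the adjusted p. Upward, beside the fibroblast median of 1.36, they were the p53 targets (median 0.30, 9 of 31 up, adjusted p = 0.174 with an estimated correlation), adhesion and homing (0.26, 12 of 32 up and 2 down, adjusted p = 0.132), FGF-ERK targets (0.31, 5 of 18 up and 1 down, adjusted p = 0.132), Nodal and BMP targets (0.08, 9 of 23 up and 2 down, adjusted p = 0.212) and primed epiblast (0.25, 6 of 17 up and 2 down, adjusted p = 0.270). So were mesoderm and primitive streak (0.10, 5 of 23 up, adjusted p = 0.213), neuroectoderm (0.08, 4 of 25 up, adjusted p = 0.206) and primitive and visceral endoderm (10 of 27 up and 1 down, adjusted p = 0.212), whose median of -0.03 had the opposite sign to its mean of 0.29 and to the test. Downward, they were cell cycle (-0.22, 9 of 37 down and 3 up, adjusted p = 0.438) and germ line (-0.20, 3 of 27 down, adjusted p = 0.212). Adjusted over the list alone, the members up and down were 13 and 0, 15 and 5, 7 and 1, 9 and 2, 7 and 3, 7 and 1, 4 and 0, 10 and 1, 3 and 13, and 0 and 3, in the same order.

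Haematopoietic regulators (3 of 36 up and 2 down; camera, adjusted p = 0.788), abundant marrow transcripts (2 of 32 up and 1 down, adjusted p = 0.788) and haemoglobins (0.943) did not pass in D10 either. The same held for the two-cell-like (0.0949), Wnt (0.215), LIF-STAT3 (0.776), endothelial (0.215) and housekeeping lists (0.963; camera, adjusted p in parentheses). Of these, the two-cell-like list, with 5 of 19 members above background, and the endothelial list passed upward with fry (adjusted p = 0.00585 and 0.0280). No chromosome passed, where camera gave 0 at an unadjusted p under 0.05 with the preset and 2 with an estimated correlation, with medians from -0.06 to 0.0017. The count of 2496 rose to 3977 with the 9 arrays counted separately and fell to 1582 with only the arrays of the groups compared. Without D10 replicate 2 it was 1188, without the merged D10 sample 1144, without ESC replicate 3 1551 and without ESC replicate 1 1625.

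In the authors' deposited table of 461 selected probe sets, 396 were higher and 65 lower in D10 than in ESC. In that table of theirs, the median fold of the higher ones was 2.39, with quartiles of 2.15 and 2.78, and the D5 mean lay between the others for 416. In the authors' larger deposited table, the step-up p was under 0.05 for 247 probe sets between ESC and D5, 2216 between ESC and D10 and 35 between D5 and D10.

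**Figure D2:**
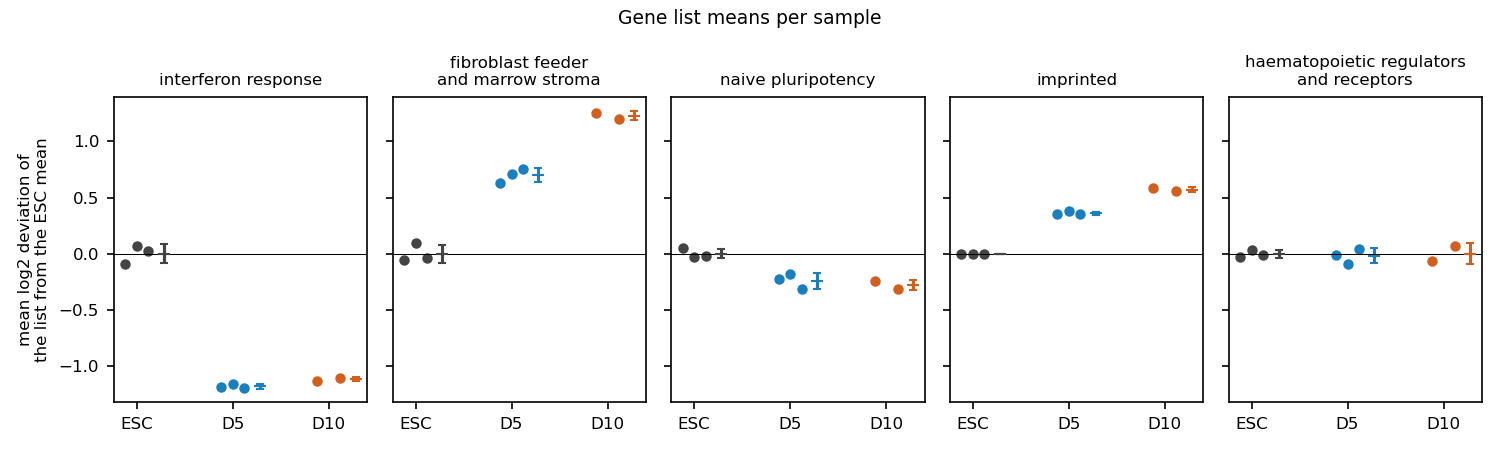
Mean log2 deviation from the ESC mean over the members of 5 gene lists (y axis), for each of 8 samples (points) with group mean and SD at the side (n = 3, 3 and 2). The interferon list lay at -1.18 ± 0.02 in D5 and -1.12 ± 0.02 in D10, and the fibroblast list at 0.70 ± 0.06 and 1.23 ± 0.04.

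The re-derived lines shared 951 changes against ESC, of 1116 called in D5 and 2496 called in D10. Of the called probe sets, 607 rose in both and 344 fell in both, with 1 in opposite directions, while independent lists would share 36.3 and 14.4. The log2 changes correlated at r = 0.774 across probe sets, which are not independent of each other. Simulated unchanged groups against the same ESC arrays gave r = 0.446, and the covariance was 0.0578 against 0.00863 simulated. With the ESC arrays split 2 and 1 between the comparisons, so that none was shared, the 6 possible splits gave covariances of 0.0468 to 0.0505, r of 0.525 to 0.578 and 153 to 404 shared changes. A state common to all ESC arrays would still enter both comparisons.

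Set against each other, the re-derived lines had few probe sets past the adjusted threshold, with n = 3 and n = 2. At an unadjusted p under 0.05 in limma there were 2814 of 28853. In D10, Peg10 was 12.1-fold higher than in D5 (limma, adjusted p = 4.50e-06), and its D5 level of 5.73 ± 0.13 (SD, n = 3) was below that of ESC. Zscan4c, a marker of the two-cell-like state of ESCs, was 3.65-fold higher in D10 (5.97 ± 0.13, SD, n = 2) than in D5 (4.10 ± 0.22, SD, n = 3). In all, 62 probe sets passed limma, 56 up and 6 down, and 23 changed at least 2-fold, 20 up and 3 down.

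The largest rises from D5 to D10 were Peg10, Uty (log2 change 2.19), Zscan4c (1.87), Has2 (1.51), the chemokine Ccl2 (1.20) and thrombomodulin, Thbd (1.18). The falls that met the rule were the neuronal factor Neurod1 (-1.11), the imprinted gene Phlda2 (-1.07) and Hmces (-0.56). Of the fixed lists' members, Pmepa1 (0.86), Thbs1 (1.03), the collagen cross-linking enzyme Lox (0.97), Runx1 (0.59), Pdgfra (0.79) and Gm4340 (1.64) also rose. Zscan4c and Gm4340 belong to multicopy families, so the values may hold signal of several copies. Uty (3.20) and Gm4340 (3.58) in D5 and Neurod1 (3.56) in D10 lay below the background level of 3.71, so their changes are lower bounds. Pou5f1 (-0.12), Nanog (0.25), Sox2 (-0.07), Zfp42 (-0.0017), Klf4 (-0.23) and Esrrb (-0.06) did not pass, except Nanog with an intensity trend and robust estimation (adjusted p = 0.0460).

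Fibroblast genes were higher in D10 than in D5, with 7 of 35 up, 28 not past the threshold and 28 up when adjusted over the list alone (median 0.57, camera, adjusted p = 2.32e-32, and adjusted p = 0.0561 with an estimated correlation). The interferon list did not pass (0 up, 0 down, median 0.05; camera, adjusted p = 0.115), nor did naive pluripotency (median -0.06, adjusted p = 0.210). Beside the fibroblast genes, 4 further lists passed camera, with adjusted p from 1.44e-06 to 0.0114, but not with an estimated correlation, for which the parentheses give the adjusted p. Imprinted genes passed with 2 up and 1 down of 38 (median 0.13, adjusted p = 0.0561 with an estimated correlation), trophoblast genes with 1 of 24 up (0.19, adjusted p = 0.0539), two-cell-like genes with 2 of 19 up (0.19, adjusted p = 0.0561) and Y-linked genes with 1 of 9 up (0.36, adjusted p = 0.109). Adjusted over the list alone, 10 imprinted genes rose and 5 fell, 6 trophoblast, 2 two-cell-like and 3 Y-linked genes rose, and 2 Y-linked genes fell.

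Another 8 lists passed camera, with adjusted p from 4.87e-06 to 0.0262, none of which held with an estimated correlation, for which the parentheses give the adjusted p. They were adhesion and homing (median 0.23, adjusted p = 0.0777 with an estimated correlation), Nodal and BMP targets (0.23, adjusted p = 0.107), antigen presentation (0.11, adjusted p = 0.0740), FGF-ERK targets (0.09, adjusted p = 0.120), primed epiblast (0.10, adjusted p = 0.322), endoderm (0.03, adjusted p = 0.360), hypoxia and glycolysis (0.06, adjusted p = 0.391) and, downward, DNA methylation and chromatin (-0.14, adjusted p = 0.360). The other lists did not pass, with adjusted p in camera of 0.0689 for mesoderm and primitive streak, 0.0959 for neuroectoderm, 0.0647 for p53 targets, 0.544 for germ line, 0.803 for haematopoietic regulators, 0.780 for marrow transcripts, 0.519 for Wnt, 0.721 for LIF-STAT3, 0.780 for cell cycle, 0.780 for haemoglobins, 0.475 for endothelial and 0.211 for housekeeping genes. No chromosome passed, where camera gave 0 at an unadjusted p under 0.05 with the preset and 0 with an estimated correlation, with medians from -0.02 to 0.01. The count of 62 was 2 with only the arrays of the groups compared and 517 with the 9 arrays counted separately. It was 18, 16 and 19 without ESC replicates 1, 2 and 3 in turn, 4, 14 and 6 without D5 replicates 1, 2 and 3, 30 and 4 without D10 replicates 1 and 2, and 3 without the merged D10 sample. Of the 15 called genes that the naming rule took in this comparison, Peg10 and Has2 alone passed in every alternative.

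**Figure D3:**
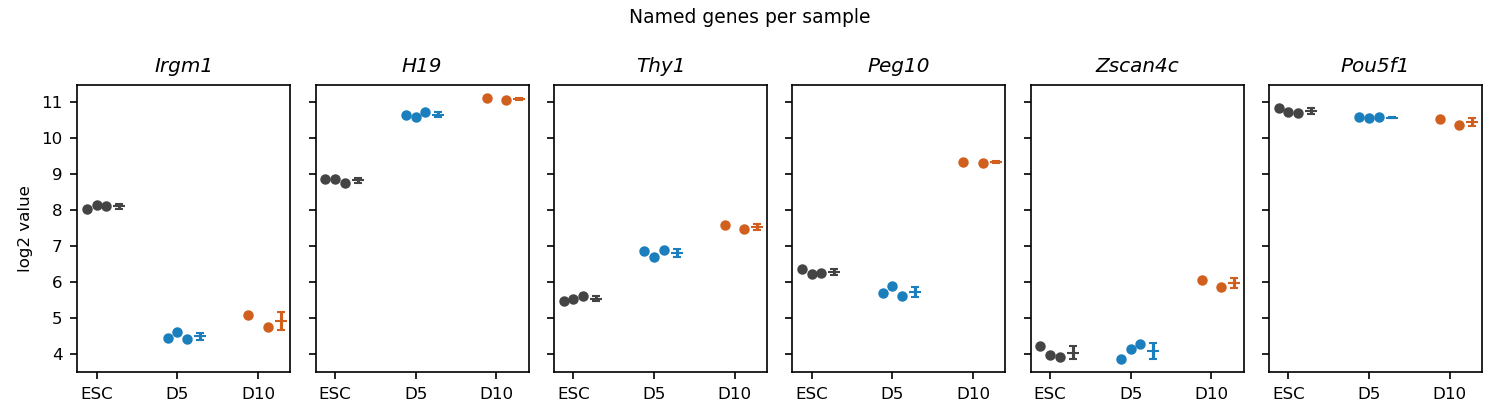
Log2 values (y axis) of 6 named genes in each of 8 samples (points), with group mean and SD at the side (n = 3 for ESC and D5 and n = 2 for D10, whose replicates 1 and 3 were averaged). Peg10 lay at 6.28 in ESC, 5.73 in D5 and 9.33 in D10, while Thy1 rose from 5.54 to 6.82 and 7.53.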

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

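All tests of explanations in this part were chosen after the results were seen. The changes of the re-derived lines against ESC differed between D10 and D5 for 62 probe sets, by limma's test of the difference itself. Among the named genes the difference on the log2 scale was 3.59 for Peg10, 2.19 for Uty, 1.87 for Zscan4c, 1.64 for Gm4340, 1.51 for Has2, 1.20 for Ccl2, 1.18 for Thbd, 1.03 for Thbs1, 0.975 for Lox, 0.862 for Pmepa1, 0.79 for Pdgfra and 0.586 for Runx1. It was -1.11 for Neurod1, -1.07 for Phlda2 and -0.564 for Hmces. Among lists past camera, the median difference was 0.566 for fibroblast genes, 0.357 for Y-linked, 0.228 for adhesion and homing and for Nodal and BMP targets, 0.19 for two-cell-like, 0.188 for trophoblast, 0.134 for imprinted and 0.109 for antigen presentation genes. It was 0.096 for primed epiblast, 0.0875 for FGF-ERK, 0.0641 for hypoxia and glycolysis, 0.0312 for endoderm and -0.139 for DNA methylation and chromatin genes. None of these list differences held with an estimated correlation.

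Fibroblast genes were higher in D5 and higher still in D10, with calls that were lost with an estimated correlation for D5 against ESC (adjusted p = 0.0514) and for D10 against D5 (0.0561). The lowest median in D10 was 1.30 over quantile normalization, median centring and the interquartile range as a covariate, against 1.36. These values argue against the remaining spread of the deposited arrays as the cause. The arrays already had medians between 4.45 and 4.53, so quantile normalization and median centring could move the list little. Normalization before deposition was not tested. A candidate explanation is more RNA from feeder cells, on which the ESCs and, after the sort, the re-derived lines grew. The test run does not decide it. Within groups the list's mean moved between samples more than that of 98.52% of 10000 random lists of like expression. But 7 of the other 26 lists reached the 95th percentile too. Of the 35 genes, 33 were above the background level in ESC too and 1 is on another list, and abundant ones rose, as Col1a1 from 8.86 to 9.80 and 10.31, but Ccn2 (7.36, 7.51 and 7.37) and Col5a2 (6.95, 7.03 and 6.92) did not pass in either comparison. Fibroblast-like cells arising within the re-derived lines would also raise fibroblast genes and stay open, untested. The list was drawn up for feeder cells and marrow stroma alike, and RNA from marrow cells was not tested as a source either. The Y-linked gene Ddx3y (4.34, 5.18 and 6.35) and Xist (4.61, 5.61 and 5.96) rose in the same lines. Whether their RNA and that of the fibroblast genes had 1 source was not tested. Whether the D10 cells, whose arrays the file headers call sorted, were sorted again before extraction is not given in the sources used here.

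Interferon-response genes were lower in both re-derived lines (medians -0.99 and -0.78), among them Irf7 (5.17 in ESC and, below the background level of 3.71, 3.35 in D5 and 3.49 in D10). Over the alternatives these medians ran from -1.18 to -0.98 in D5 and from -1.18 to -0.74 in D10. Fewer feeder cells of unchanged interferon activity would lower fibroblast genes too, but their median rose by 0.80 on the log2 scale in D5. This cannot exclude feeder cells that were less interferon-active, and the source of the fibroblast rise is itself undecided. No single ESC array accounts for the lower interferon genes, since at least 97.4% of the median change remained without any 1 of them. A biological difference between the transplanted line and the lines that passed through marrow stays open, untested. A passing state of the ESC cultures on the day of harvest was not tested and is confounded with the group.

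Peg10 was far higher in D10 than in the other groups. If the D5 fibroblast rise came from feeder cells that carried Peg10 alike in both lines, Peg10 would rise in D5 too. Instead Peg10 changed by -0.55 there (limma, adjusted p = 0.0151, and from 0.00327 to 0.0665 over the alternatives, over 0.05 without ESC replicate 1 or 3 or D5 replicate 1 or 3). The source of the fibroblast rise is undecided, so feeder RNA is not excluded for Peg10 in D10. No single D10 sample accounts for the Peg10 rise, as the change against ESC was at least 3.03 with either D10 sample alone. A biological change in the D10 line stays open, untested. With 1 line described per day after transplantation, the day and the line cannot be separated.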

How the results depend on the processing

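The alternatives with 9 arrays, the interquartile range and the t-test, the chromosomes with only genes above background, the split of the ESC arrays and the counts over splits, were chosen after seeing the data. The t-test was run for counts of probe sets only, not for named genes, lists or chromosomes. No named gene or list passed in opposite directions in different alternatives, and no chromosome passed in any. Signs did change for Klf4 in D5 against ESC (-0.06 to 0.06) and Zfp42 (-0.11 to 0.11) and Esrrb (-0.15 to 0.03) in D10 against D5, which did not pass, and for the medians of lists that passed: neuroectoderm in D5 against ESC (-0.02 to 0.09), and endoderm in D10 against ESC (-0.11 to 0.17) and in D10 against D5 (-0.04 to 0.15). Other medians kept their sign but moved. In D10 against ESC they included trophoblast (0.29 to 0.54), FGF-ERK (0.18 to 0.38) and primed epiblast (0.19 to 0.40). So did germ line (-0.25 to -0.08), cell cycle (-0.26 to -0.10) and Y-linked genes (0.22 to 0.71). In D10 against D5 the Y-linked median ran from 0.18 to 0.50. Past the threshold in every alternative run by gene were 32 of 57 called genes in D5 against ESC, 43 of 57 in D10 against ESC and 2 of 15 in D10 against D5. Of the genes not called, Pou5f1 passed in D5 against ESC with a trend and robust estimation, and in D10 against ESC with that, quantile normalization, 9 arrays and the interquartile range, and Nanog passed with a trend and robust estimation in D10 against ESC and in D10 against D5. With an estimated correlation, the lists past camera went from 14 to 3 in D5 against ESC and from 18 to 4 in D10 against ESC. In D10 against D5 they went from 13 to 0. That form of camera allows for correlated members but also tests on fewer degrees of freedom. The drop therefore cannot be credited to correlated members alone. With fry, 12, 20 and 9 lists passed, 11, 17 and 9 of them shared with camera, and the others were FGF-ERK targets in D5 against ESC, and two-cell-like, antigen presentation and endothelial genes in D10 against ESC. Other lists not past the main test passed in some alternative fit. These were mesoderm in D5 against ESC, and naive pluripotency, mesoderm, neuroectoderm and p53 targets in D10 against D5. Called probe sets in D5 against ESC (1116) were 1695 with a trend and robust estimation and 247 with the t-test. In D10 against ESC (2496) they were 1582 with only the arrays of the groups compared, which has fewer samples, and 3977 with 9 arrays. In D10 against D5 (62) they were 154 without the lowest 30%, 268 with a trend and robust estimation, 2 with only the groups compared, 29 with array weights, 193 with the replicate block over 9 arrays, 517 with 9 arrays and 35 with the t-test. Where not stated, the cause was not tested. The other alternatives with all samples stayed within 1.5 times.

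Leaving out samples in turn, with fewer samples each time, gave 457 (without ESC replicate 3) to 1091 probe sets in D5 against ESC, 1144 (without the merged D10 sample) to 2507 in D10 against ESC, and 3 (without the merged D10 sample) to 56 in D10 against D5. Changes shared by both lines (951) numbered 417 to 927: 489, 579 and 417 without ESC replicates 1, 2 and 3, 460, 540 and 507 without D5 replicates 1, 2 and 3, 616 without D10 replicate 2 and 596 without the merged D10 sample. With no ESC array shared, and so fewer controls for each line, they numbered 383, 404 and 344 with D10 set against ESC replicate 1, 2 or 3 alone and D5 against the others, and 184, 153 and 198 with D5 set against 1 of them alone. Lists numbered 12 to 15, 13 to 18 and 11 to 16, in the same order. With 1 D10 sample left, it is assumed to vary like the other groups. Same-numbered arrays deviated from their group means with correlations from -0.30 to 0.19, and 2 of 9 correlated best with their own number. This gave no sign that the numbers pair the samples. It cannot exclude pairing, because deviations from a group mean depend on each other and D10 replicates 1 and 3 were near-identical. The replicate block gave 938, 3199 and 193 probe sets. Of the 10 splits of the ESC and D5 arrays, 1 gave as many probe sets as the real 1116 (highest other 0), 1 as many lists as the real 14 (highest other 11), and 10 as many chromosomes as the real 0 (highest other 0). These 10 splits are too few for a share under 0.05. Dim genes are limited by the background level of 3.71. Adding a pseudocount was not run because the values were on a log scale, and the other table held identical values.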

Other observations

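Single genes of the signalling and lineage lists moved in both re-derived lines. The Nodal target Lefty2 fell by 1.03 in D5 and 1.38 in D10 on the log2 scale, and the cyclin Ccnd2 rose by 0.90 and 1.30 (limma, each past the adjusted threshold). The p53 targets Cdkn1a (0.56 and 0.97, the D5 call being lost with the replicate block and without some of the samples) and Mdm2 (0.58 and 0.58) rose. The follistatin gene Fst rose by 1.25 and 2.01, the adhesion receptor Cd44 by 1.23 and 1.79, and the receptor gene Pdgfra by 0.64 and 1.43, beside the fibroblast medians of 0.80 and 1.36. Among haematopoietic regulators Ebf1 rose by 0.95 and 1.57, with 1 of its 2 probe sets past the threshold upward in D5. Ptpn6 fell by 0.75 (its call lost without some of the samples, highest adjusted p = 0.0526) and 0.85, and Laptm5 fell by 1.29 in D10.

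Xist, the X-inactivation RNA, was at 4.61 ± 0.09 in ESC, 5.61 ± 0.06 in D5 and 5.96 ± 0.32 in D10 (SD, n = 3, 3 and 2), so it rose in the same lines as the Y-linked gene Ddx3y. Sgce, the imprinted neighbour of Peg10, was at 3.70 ± 0.16, 4.31 ± 0.02 and 5.21 ± 0.44 (SD, n = 3, 3 and 2), with limma's adjusted p = 0.0710 in D5 and 0.00112 in D10 against ESC.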
